A study of Mus musculus with 6 samples.

How the data were processed

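Total RNA of olfactory epithelium from 3 C57Bl/6 mice was hybridised to Affymetrix Mouse Exon 1.0 ST arrays, per the labels, 5 days after unilateral naris occlusion. The deposited values are on the log2 scale and were made by the authors with RMA in Expression Console at the core gene level, per the labels; the log2 base follows from their range, and the software version is not given in the sources used here. RMA as a method corrects background, makes probe distributions alike across arrays and summarises probes by median polish, which can shrink differences that affect many genes at once. The array medians of the deposited values were not equal, and other scalings were among the alternatives. Scanner files were not used here, and no depth applies to arrays.

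The labels place 3 arrays on the occluded (ipsilateral) and 3 on the contralateral side. Probe sets were named from the platform annotation paired with the series. Of 23332 probe sets, 14996 carried 1 gene symbol, 1019 several and 7317 none; 14941 of the single symbols matched a gene of the reference table by Entrez identifier and 0 symbols needed updating. No gene was named from a probe set with several symbols. All probe sets were tested; 135 symbols had more than 1 probe set, and lists used the probe set with the highest mean over all 6 arrays.

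The sides were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no replicate block), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Differences are occluded minus contralateral on the log2 scale. An exact permutation test of 3 against 3 cannot go below p = 0.1 (two-sided), so none was used for single genes. The 36 gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry, which asks whether a list moves on balance one way and compares it with no other genes. For each list, passing members were counted over all probe sets and adjusted over the list alone.

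The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per direction, all passing genes or, where fewer than 8 passed, the 8 with the smallest unadjusted p; the 3 members of each list with the smallest p; 15 landmark genes; and the 5 odorant receptors with the smallest p in each direction. Not every gene so taken is printed. The lists covered activity-linked genes, immediate early genes, neuronal stages, epithelial, glandular, glial, vascular, immune and connective tissue cells, blood, stress and metabolism, receptor families, ribosomal and oxidative phosphorylation genes, and a background reference of genes not expected in nasal tissue. The landmark gene Kirrel2 was not analysed here.

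The fit was tested on simulated data: over 20 simulations of 23332 probe sets with the spreads of these arrays, 50 of them changed at each of 4 sizes at once, it made on average 6.5 false calls and recovered 4.1% of probe sets changed 1.41-fold, 63.5% of those changed 2-fold, 88.8% at 2.83-fold and 93.9% at 4-fold. Other numbers of changed probe sets were not simulated, so these shares are not the chance that a single changed gene is called. A shift of 0.3 in a list was recovered by camera in 20 of 20, with independent genes. Alternatives were a fixed or random replicate block, leaving out each array, 3 other scalings (median centring, quantile normalization once more, cyclic loess), filters on low probe sets, probe sets with 1 symbol only, eBayes with a trend or robust, array quality weights, other thresholds, and other list settings. The weight estimation stopped before reaching its convergence tolerance, with weights from 0.217 for occluded replicate 1 to 7.02 for occluded replicate 3. The closing tests used bootstrap standard errors of medians from 10000 draws. The draws were over genes within fixed arrays, so these errors hold no spread between arrays and treat genes as independent.

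The criteria of 4 closing tests were rewritten after their values had been seen. For the zone test of occluded replicate 1, the condition that the value exceed its spread was added. For the mature neuron test, the gap was first set against 2 bootstrap standard errors of the difference, which it did not reach, then against the SD of the mature neuron members, which it exceeded, then against the first bound again, and at last against the SD. For the tests of cyclic loess and of occluded replicate 1 on the connective tissue, endothelium, macrophage and neutrophil lists, the median of all genes was subtracted from the lists' median, since both settings move it; on the earlier, unsubtracted scale neither test had reached its bound. The bound for occluded replicate 1, first 0.5 of the full value, which the value did not clear by 2 standard errors, was then set to 0, as an array that made the whole pattern would leave none of it.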

Results

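Expression was measured in mouse olfactory epithelium, the nasal tissue that holds the odorant-sensing neurons, 5 days after one nostril had been closed. Closing a single nostril lowers odour stimulation of the epithelium on the closed side and, per the labels, raises it on the open side, so the open side was not an untreated reference. The study used 3 C57Bl/6 mice, and 6 arrays were analysed, 3 from the occluded side and 3 from the contralateral side. The labels do not say which arrays came from the same mouse, and p-values measure the spread between these arrays. The median log2 value per array lay between 7.94 and 8.12 over 23332 probe sets, and no 2 arrays held identical values. Occluded replicate 1 stood apart from the others, with correlations of 0.977 to 0.983 across probe sets, against 0.986 to 0.989 among the remaining arrays. The number of arrays limits the precision of every value below.

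The comparison of the occluded with the contralateral side asks which genes depend on odour-evoked activity. S100a5, a calcium-binding protein of mature olfactory sensory neurons, had the smallest p-value of all probe sets, with a mean log2 value of 10.17 ± 0.25 (SD, n = 3) on the occluded side and 12.01 ± 0.22 (SD, n = 3) on the contralateral side. Its log2 difference was -1.85 (SE 0.17), a 3.59-fold lower level with a 95% interval of 2.72 to 4.74, and all occluded-side arrays lay below all contralateral ones. The limma adjusted p over all probe sets was 0.221, so S100a5 did not pass the threshold of 0.05. Pcp4l1, a small neuronal protein with an IQ motif, had a log2 difference of -0.92 (SE 0.17), and Rasgrp4, a guanine nucleotide exchange factor for Ras, one of -0.85 (SE 0.12). Slc17a6, the vesicular glutamate transporter of olfactory sensory neurons, had a log2 difference of -0.52 (SE 0.09).

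No probe set passed over the whole array: limma with Benjamini-Hochberg adjustment called 0 probe sets, 0 higher and 0 lower. At an unadjusted p under 0.05 there were 1233 probe sets, 890 higher and 343 lower on the occluded side, where chance alone would give 1166.6. The sides did not overlap in 2502 probe sets, or 10.7%, where chance gives 10%. The median log2 difference of all probe sets was 0.06. Centring each array on its median moved that median to -0.02 and, with it, the balance of the unadjusted calls, to 510 higher and 873 lower. Cyclic loess moved it to -0.00059 and gave 800 higher and 535 lower. Testing only probe sets with 1 gene symbol gave 1 call, S100a5, at an adjusted p of 0.0382 by limma, and array quality weights, whose estimation did not converge, gave 62 calls; the adjusted p of S100a5 ranged from 0.00701 to 0.831 over the alternatives.

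Of the 13 measured activity-linked neuron genes, 6 fell and 2 rose when p-values were adjusted over the list alone, and 0 passed over all probe sets. This list drew in part on published work with nostril closure, this series included, so that count is not independent evidence of its direction. The 6 lower genes were S100a5, Pcp4l1, Rasgrp4, Slc17a6, Lrrc3b and Pcdh10. Lrrc3b, a leucine-rich repeat membrane protein, had a log2 difference of -0.62 (SE 0.16), and Pcdh10, a protocadherin of cell adhesion, one of -0.47 (SE 0.11). The 2 higher genes were Efna5, an ephrin ligand of axon guidance, at 0.41 (SE 0.10), and Cnga2, a subunit of the olfactory cyclic nucleotide-gated channel, at 0.26 (SE 0.09). The other members did not pass: Sema7a, an axon guidance protein, was at -0.28 (SE 0.18), the neurotrophin Bdnf at -0.03 (SE 0.09), the histone gene H2bc21 at 0.10 (SE 0.09), the plexin Plxna1 at 0.06 (SE 0.10) and Doc2g at 0.02 (SE 0.08). The median log2 difference of the list was -0.28, and camera with its preset correlation gave an adjusted p of 2.36e-08, which for the same reason is not independent evidence. With an estimated correlation the adjusted p = 0.795, and fry gave 0.274, or 0.00866 in its mixed form, which ignores direction. The median was -0.45 without occluded replicate 1, where 7 fell and 1 rose over the list alone, and -0.17 without contralateral replicate 3. Over the list alone 1 rather than 2 rose with the replicate block, with centring, and without any 1 array except contralateral replicate 3. Leaving out members that another list also holds ended the camera call (adjusted p 0.121). That left only Lrrc3b and H2bc21, so it cannot speak to the list.

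**Figure D1:**
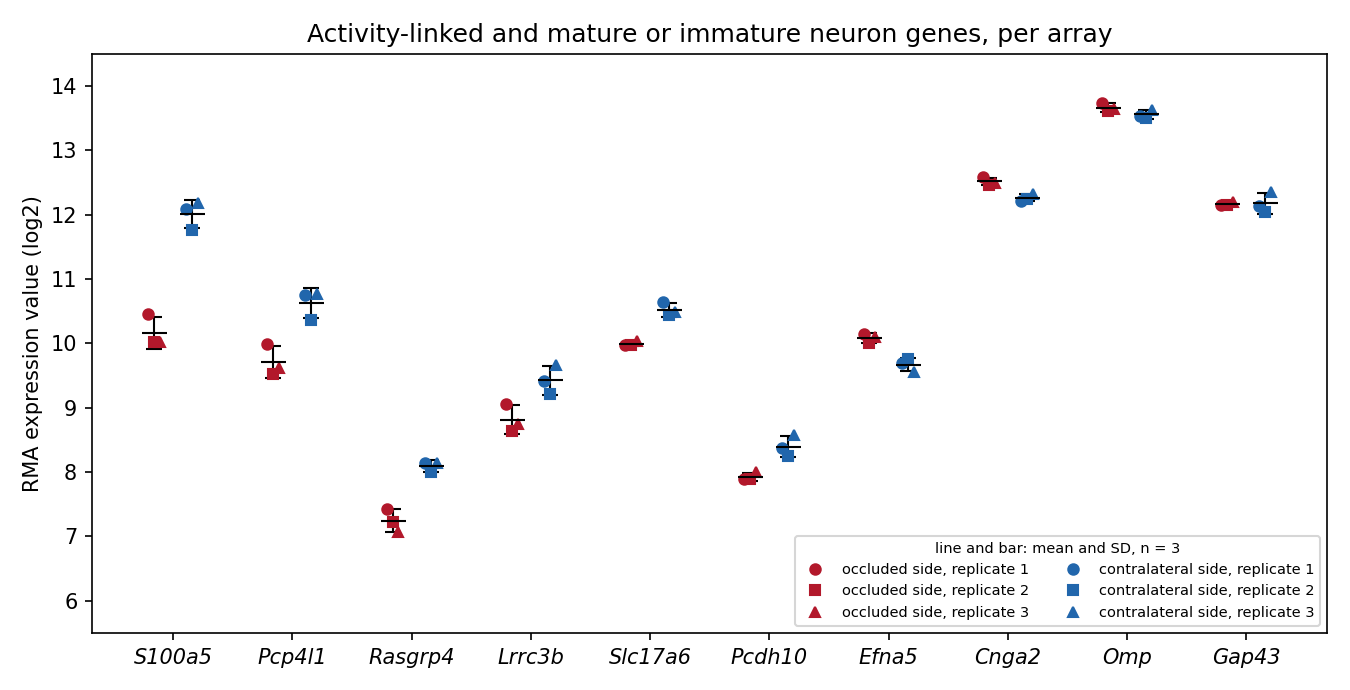
RMA expression values (log2, vertical axis) of 10 genes in each of the 6 arrays, with occluded-side arrays in red, contralateral arrays in blue, a marker shape per replicate number, and lines and bars for the mean and SD (n = 3). S100a5 lay between 10.02 and 10.46 on the occluded side and between 11.76 and 12.19 on the contralateral side, whereas Omp lay between 13.51 and 13.74 in all 6 arrays.

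Markers of mature olfactory sensory neurons had small log2 differences between the sides. Omp, the olfactory marker protein of mature neurons, had a log2 difference of 0.11 (SE 0.09), Adcy3, the adenylyl cyclase of odour transduction, one of 0.15 (SE 0.11), and Gnal, the olfactory G protein subunit, one of 0.14 (SE 0.08). In the odorant transduction and mature neuron list, 24 of 31 members lay above 0 and 7 below, with a median of 0.10 and a camera adjusted p of 0.400. Without occluded replicate 1 that median was 0.07 and Adcy3 0.06, and without occluded replicate 2 Adcy3 was 0.23. The 1 member that passed over the list alone, Slc8a1, a sodium-calcium exchanger, was at -0.59 (SE 0.09); Pde1c, a phosphodiesterase of olfactory cilia, was at -0.25 (SE 0.09). Gap43, a growth-cone protein of immature neurons, was at -0.01 (SE 0.11), and its sign turned without contralateral replicate 3 and with array weights. In the immature neuron list 21 of 25 members lay below 0, with a median of -0.04 and a camera adjusted p of 0.000519, and the adjusted p = 0.957 with an estimated correlation. Its examples were Elavl4, a neuronal RNA-binding protein, at -0.19 (SE 0.09), and Ebf1, a transcription factor of olfactory neurons, at -0.13 (SE 0.08). Gng3, also among the members with the smallest p, went the other way, at 0.18 (SE 0.10). Without occluded replicate 2 the median of that list was 0.03 and the adjusted p 0.0687.

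Outside the activity-linked list, the genes with the smallest unadjusted p did not pass over all probe sets, and only their values are given. On the lower side, Eml5, a microtubule-associated protein, had a log2 difference of -0.88 (SE 0.13), Slc8a1 one of -0.59 (SE 0.09), and Nphs1, a cell adhesion protein best known from the kidney filter, one of -0.42 (SE 0.08). On the higher side, Rps27l, a ribosomal protein-like gene, was at 0.76 (SE 0.14), Tubb2a, a neuronal beta-tubulin, at 0.74 (SE 0.13), Ngp, a neutrophil granule protein, at 0.79 (SE 0.15), Rims3, a protein of the presynaptic release site, at 0.56 (SE 0.11), Cck, the neuropeptide cholecystokinin, at 0.54 (SE 0.10), and Fbp1, an enzyme of gluconeogenesis, at 0.47 (SE 0.09). The limma adjusted p of these genes lay between 0.593 and 0.805. A second Slc8a1 probe set gave -0.60 at a mean level of 5.83, under the 5.90 of background reference genes.

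The connective tissue, endothelium, macrophage and neutrophil lists lay higher on the occluded side by camera. All 39 measured genes of connective tissue, cartilage and bone had a log2 difference above 0, with a median of 0.32 and a camera adjusted p of 2.85e-08; with an estimated correlation the adjusted p = 0.957. Dmp1, a protein of bone matrix, was at 0.71 (SE 0.20), Ctsk, the collagen-degrading protease of osteoclasts, at 0.51 (SE 0.18), and Sparc, a matrix glycoprotein, at 0.41 (SE 0.14). In the endothelium list 24 of 25 members lay above 0, with a median of 0.25 and an adjusted p of 0.000476, and the adjusted p = 0.957 with an estimated correlation. Emcn, a sialomucin of blood vessels, was at 0.37 (SE 0.15), and Kdr, the main VEGF receptor, at 0.39 (SE 0.17). The macrophage and monocyte list had a median of 0.22 and an adjusted p of 0.0162 (with an estimated correlation the adjusted p = 0.957), with the immune adaptor Tyrobp at 0.62 (SE 0.20) and the lipopolysaccharide co-receptor Cd14 at 0.38 (SE 0.13). The neutrophil list had a median of 0.21 and an adjusted p of 0.0314 (with an estimated correlation the adjusted p = 0.900), and its 1 member past the test over the list alone was Ngp. These values leaned on occluded replicate 1: without it 34 of the 39 connective tissue genes lay above 0, and the medians were 0.16 for connective tissue, 0.11 for endothelium, 0.12 for neutrophils and 0.08 for macrophages, the last no longer past camera (adjusted p 0.106). The macrophage median was 0.12 without contralateral replicate 2, and its call ended without contralateral replicate 3 (0.0662). The neutrophil call ended without occluded replicate 2 (0.156) or contralateral replicate 3 (0.105) and when dim probe sets were left out (0.0964). With each array centred on its median the medians were 0.24 for connective tissue, 0.17 for endothelium, 0.14 for macrophages and 0.13 for neutrophils.

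Genes of energy metabolism and protein synthesis also lay higher. In the oxidative phosphorylation list 58 of 62 members were above 0, with a median of 0.22 and a camera adjusted p of 2.85e-08; with an estimated correlation the adjusted p = 0.957. The complex I subunits Ndufa7, Ndufa6 and Ndufa5 were at 0.74 (SE 0.19), 0.37 (SE 0.10) and 0.33 (SE 0.10). In the cytosolic ribosomal protein list 17 of 20 members were above 0, with a median of 0.21 and an adjusted p of 0.0162 (with an estimated correlation the adjusted p = 0.957), and 2 members, Rpl4 and Rps27l, passed over the list alone. Rplp0 was at 0.27 (SE 0.11). The mean level of Rpl4, 5.29, lay under the median of the background reference genes, 5.90, so the size of its difference, 1.03 (SE 0.20), is not well measured. Without occluded replicate 1 the medians were 0.14 and 0.12, and the ribosomal call ended without occluded replicate 2 (adjusted p 0.0509) and without the lowest 25% of probe sets (0.0814). With each array centred on its median both were 0.14, and after cyclic loess both were 0.15.

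The synaptic vesicle and release list went down by camera, with an adjusted p of 0.0288, although its median was 0.01 and 20 of 39 members lay above 0. Its median turned negative, at -0.07 to -0.06, under all 3 other scalings, its call ended without contralateral replicate 1 (0.143) or occluded replicate 2 (0.258), and with an estimated correlation the adjusted p = 0.957. Syt4, a synaptotagmin of vesicle release, was at -0.42 (SE 0.13) and Snap25, a SNARE protein, at -0.28 (SE 0.10), while Rims3 was at 0.56; over the list alone 1 member fell, Slc17a6, and 1 rose, Rims3. The vomeronasal receptor list, whose 82 members had a median level of 3.98, had a median of -0.10 and a camera adjusted p of 9.76e-09, and it was the 1 list still past the threshold with an estimated correlation (adjusted p = 0.0380). Its median ran from -0.30 without the lowest 25% of probe sets to -0.05 with array weights, and fry gave an adjusted p of 0.274. The level of 3.98 lay under the 5.90 of the background reference genes, so the difference of this list is not well measured. The background reference list of genes not expected in nasal tissue, with a median level of 5.90, had a median of -0.04 and an adjusted p of 0.000428, and the adjusted p = 0.900 with an estimated correlation; cyclic loess ended its call (0.0757).

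**Figure D2:**
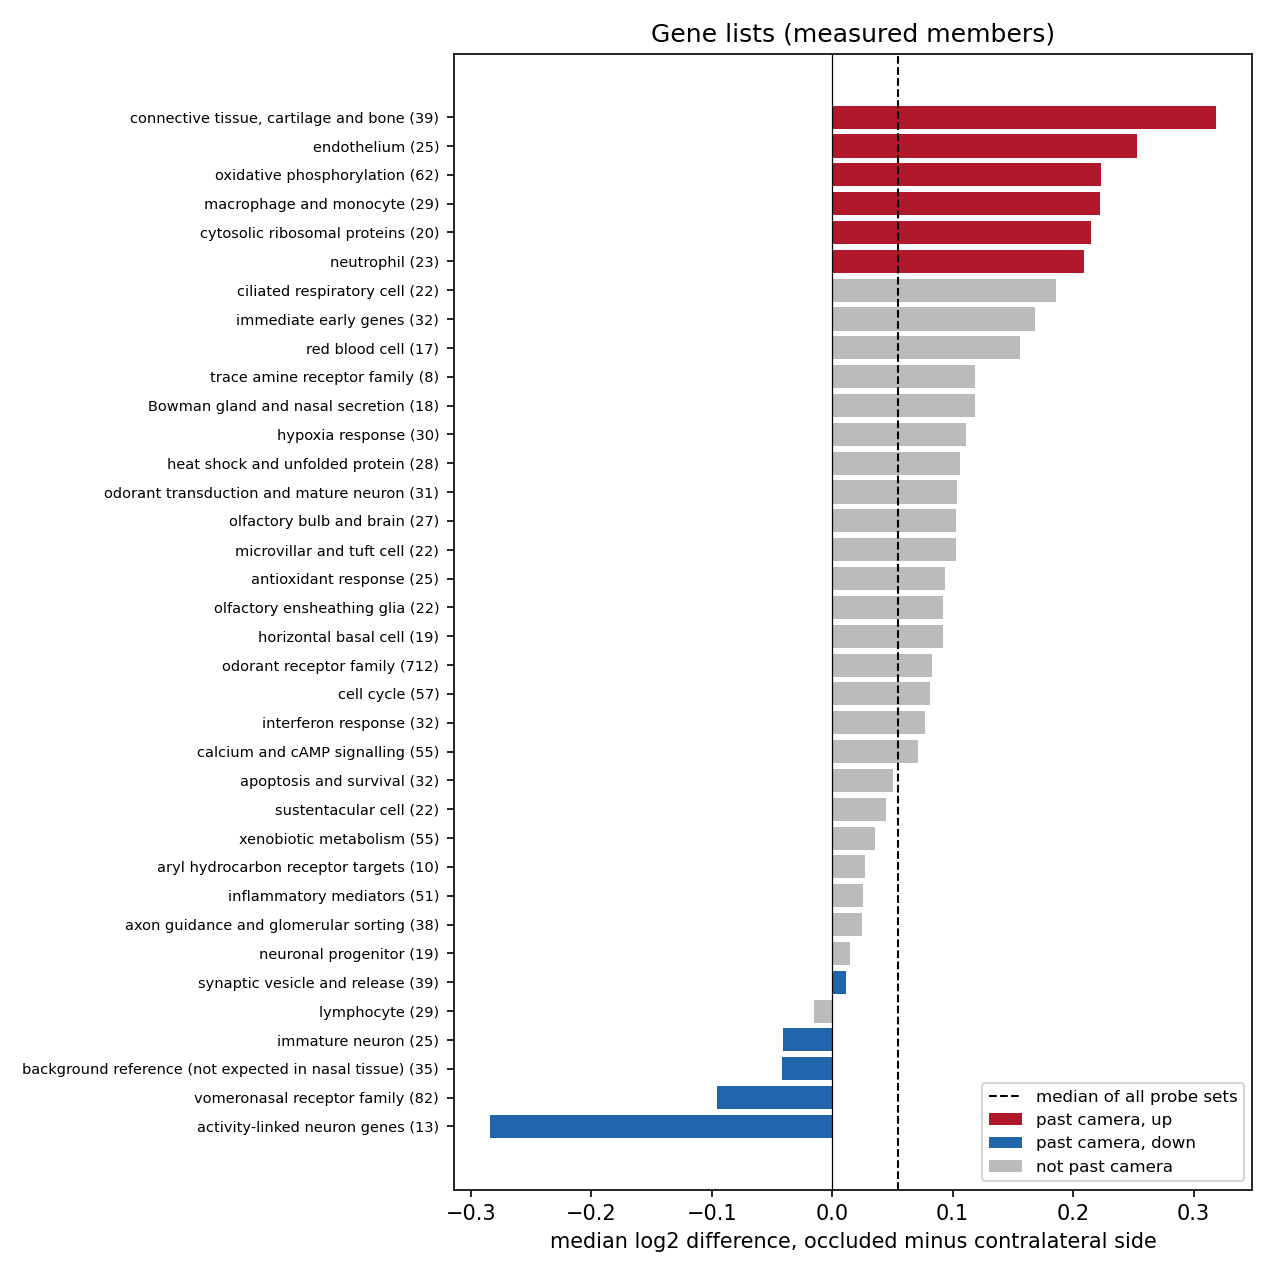
Median log2 difference of each of the 36 gene lists (horizontal axis, occluded minus contralateral side), with the number of measured members in brackets and the dashed line at the median of all probe sets, 0.06. Bars are coloured where camera with the preset correlation passed, 6 lists up and 5 down, and the medians run from -0.28 for the activity-linked genes to 0.32 for connective tissue, cartilage and bone.

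Odorant receptors, the receptors whose stimulation the occlusion lowers, were covered by 713 probe sets. None passed the test: limma called 0 over all probe sets and 0 when adjusted over the list alone, where the smallest adjusted p was 0.176. At an unadjusted p under 0.05 there were 66, of which 51 were higher and 15 lower on the occluded side, or 9.26% against 5.16% of all other probe sets. The share whose sides did not overlap went the other way, at 9.40% against 10.8% of other probe sets, where chance gives 10%. Olfr263 was at 0.86 (SE 0.17) and Olfr1387 at 0.67 (SE 0.13); Olfr1032, at 0.77 (SE 0.11), had a mean level of 5.26, under the 5.90 of the background reference genes. On the lower side Olfr855 was at -0.72 (SE 0.13), Olfr1123 at -0.40 (SE 0.10) and Olfr267 at -0.52 (SE 0.15). Near-identical receptor genes can share probes, so values of single receptors are uncertain. The median over the family was 0.08 with a camera adjusted p of 0.710; centring each array on its median brought it to 0.00. Relative to other genes the family went opposite ways as arrays were left out. Without occluded replicate 1 it was up, at 0.15 against 0.02 for all probe sets (adjusted p 1.35e-07); the median of the 93 class I receptors then went from 0.07 to 0.37, and that of the 620 others from 0.09 to 0.10. Further, without occluded replicate 2 the family was down, at 0.07 against 0.08 (adjusted p 0.0183).

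Immediate early genes, which are switched on within minutes of neuronal activity, had a median of 0.17, with 28 of 32 members above 0 and a camera adjusted p of 0.0754. Fos was at 0.23 (SE 0.17), Egr1 at 0.24 (SE 0.15) and Nr4a2 at 0.34 (SE 0.15), and 0 members passed over the list alone. Without occluded replicate 1 the median was 0.05 (adjusted p 0.501), Fos 0.09 and Egr1 0.09. The list passed camera in 6 of 19 alternatives, among them leaving out contralateral replicate 2 (0.0493), occluded replicate 3 (0.0303) or contralateral replicate 3 (0.0128), and its adjusted p = 0.957 with an estimated correlation. In the axon guidance list the median was 0.02 (adjusted p 0.177), and its sign turned under the 3 other scalings; Epha5, an ephrin receptor, was at -0.47 (SE 0.11) and Nrp1, a semaphorin co-receptor, at -0.06 (SE 0.08). The horizontal basal cell list had a median of 0.09 (adjusted p 0.421), or 0.0038 without occluded replicate 1, with the basal keratin Krt5 at 0.04 (SE 0.17), and the sustentacular cell list one of 0.04 (adjusted p 0.746), or 0.0051 without occluded replicate 1. Cyp2g1, a cytochrome P450 of supporting cells and glands, was at -0.06 (SE 0.08). The sign of Krt5 turned without occluded replicate 1 (-0.09), without contralateral replicate 2 and under the 3 other scalings, and Krt5 was at 0.19 without occluded replicate 2. The sign of the sustentacular median turned under the 3 other scalings.

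No other list passed camera. Lists of neuronal renewal had medians of 0.01 for neuronal progenitors (adjusted p 0.345) and 0.08 for the cell cycle (0.854). The medians were 0.04 for xenobiotic metabolism (0.788), 0.03 for aryl hydrocarbon receptor targets (0.626) and 0.09 for the antioxidant response (0.883). The calcium and cAMP signalling list had a median of 0.07 and a mean of 0.00 (adjusted p 0.604), and 3 of its members fell over the list alone, S100a5, Rasgrp4 and Pcp4l1, which the activity-linked list also holds. Lists of hypoxia, heat shock and unfolded protein, and apoptosis and survival had medians of 0.11 (0.177), 0.11 (0.154) and 0.05 (0.723). Ciliated respiratory cells had 0.19 (0.177), microvillar and tuft cells 0.10 (0.706), olfactory ensheathing glia 0.09 (0.140), and olfactory bulb and brain 0.10 (0.713). The lymphocyte median was -0.01 with a mean of 0.01 (0.0603), the interferon response median 0.08 (0.739) and the inflammatory mediator median 0.03 (0.331). The trace amine receptor median was 0.12 (0.859). Centring each array on its median turned the sign of the progenitor, xenobiotic, aryl hydrocarbon receptor, interferon, inflammatory, apoptosis and calcium medians. That scaling moved the median of all probe sets from 0.06 to -0.02, so small medians turned with it. Cyclic loess and quantile normalization turned the sign of the cell cycle median. Without occluded replicate 1 the hypoxia median was 0.04, and the apoptosis, cell cycle and inflammatory medians were -0.01, -0.03 and -0.01. The microvillar, antioxidant, interferon and heat shock medians were then 0.03, 0.02, 0.01 and 0.06. The lymphocyte list passed downwards without the lowest 25% of probe sets (0.00821), and ciliated respiratory cells passed without contralateral replicate 3 (0.000376). Without occluded replicate 1 camera passed 17 lists, among them trace amine receptors at a median of 0.27 (adjusted p 0.00488), ciliated respiratory cells at 0.14 (0.00326) and neuronal progenitors at -0.06 (0.00867).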

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

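The counts of 0 changed probe sets and 0 changed odorant receptors by limma held under most alternatives. Leaving out 1 array gave 0 to 1 calls and 0 to 1 higher; the 1 call, without contralateral replicate 2, was a probe set with no single gene symbol. Testing only probe sets with 1 symbol gave 1 call, 1 lower, S100a5, whose SE went from 0.168 to 0.157 as the variances were moderated anew. Array quality weights gave 62 calls, 41 higher and 21 lower, with 10 odorant receptors; occluded replicate 3 then had a weight of 7.02 and the weight estimation did not converge. Unadjusted p under 0.05 with at least 1.5-fold gave 268, 209 higher and 59 lower, with no correction for the number of tests. Unadjusted calls ran from 778 to 1704 without 1 array.

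The 11 lists past camera became 1 with an estimated correlation and 0 with directional fry, and 8 to 17 without 1 array. The mixed form of fry, which ignores direction, passed the activity-linked (adjusted p 0.00866), calcium and cAMP signalling (3.87e-06) and ribosomal protein lists (0.0492). The activity-linked list drew in part on this series and shares members with the calcium list. The activity-linked median of -0.28 lost its call with an estimated correlation (adjusted p 0.795) and with fry (0.274). Without shared members only Lrrc3b and H2bc21 were left (median -0.26, camera adjusted p 0.121), too few to speak to the list. The odorant receptor list passed upwards with array weights at 0.19 (0.00447), and without 1 array ran from 0.051 to 0.15. Signs turned for synaptic vesicle genes, at -0.068 centred, -0.064 after quantile normalization, -0.074 after loess and -0.0067 with weights, and from -0.056 (without occluded replicate 1) to 0.056 without 1 array. They also turned for immature neurons, which ran from -0.11 to 0.029 (without occluded replicate 2), for neuronal progenitors, from -0.061 (without occluded replicate 1) to 0.10, and for the cell cycle at -0.026 with weights. The 3 other scalings also lowered the median of all probe sets, from 0.06 to -0.02 centred, -0.0061 after quantile normalization and -0.00059 after loess. The synaptic median, near 0, turned with that shift. The cause of the other turns was not tested. Of 1130 values of 67 named genes under the alternatives, 1113 kept their side of the threshold, 16 passed it, and 1, of Doc2g, moved. As no named gene passed in the main fit, keeping its side means only that a value still did not pass. The sign turned in 5 settings for Krt5, in 3 each for Doc2g and Plxna1, and in 2 each for Bdnf and Gap43.

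Samples with the same replicate number did not deviate together (correlations 0.00949, 0.166 and -0.041), and only replicate 2 of the occluded side correlated best with its own number. With the replicate block limma called 0 probe sets, the smallest adjusted p was 0.544, 1271 had an unadjusted p under 0.05, and 13 lists passed camera, the immediate early and red blood cell lists being gained (adjusted p 0.0496 for both). Probe sets below 5.90, the median of the background reference genes, numbered 3586, and changes there are the least measurable.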

Other observations

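The tests of array intensity, mature neurons, neuron share, occluded replicate 1 alone and receptor expression level were chosen after the results had been seen; the splits were planned for counts of probe sets and applied to lists and odorant receptors afterwards, and the zone markers of occluded replicate 1 were chosen before their values were looked at, though their criterion was amended afterwards. Single genes of other lists also had wide differences. Bpifb5, a secreted protein of nasal glands, had a log2 difference of 2.42 (SE 0.79), with values of 9.45, 12.53 and 10.07 on the occluded side and 7.56, 8.33 and 8.90 on the contralateral side; its limma adjusted p was 0.823, and the difference ran from 1.49 without occluded replicate 2 to 3.04 without occluded replicate 1. The gland and nasal secretion list had a median of 0.12, a mean of 0.28 and a camera adjusted p of 0.527, and without occluded replicate 1 the median was 0.14 with an adjusted p of 0.000768. Alas2, an enzyme of haem synthesis in red blood cells, was at 0.69 (SE 0.27), and the red blood cell list had a median of 0.16 and an adjusted p of 0.143. Without occluded replicate 2 these were 0.44 for Alas2 and 0.07 for the list (0.791), while the list passed camera without occluded replicate 1 at 0.18 (0.000912) and without contralateral replicate 2 at 0.16 (0.0434).

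The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For adjusted calls the comparison says nothing, since with a real count of 0 all 10 splits must give as many (highest other 0). At an unadjusted p under 0.05, 3 splits gave as many. The real split gave 1233 and the highest other 2348, with occluded replicates 1 and 3 and contralateral replicate 3 on one side. The count therefore does not set the sides apart from other groupings of the arrays, and the cause of the higher count was not tested. For lists past camera, 2 splits gave as many, 11 in the real one and 11 in the highest other.

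Of the 13 activity-linked genes 8 lay lower and 5 higher on the occluded side, and the list was down by camera, a call lost with an estimated correlation (adjusted p = 0.795) and with fry (0.274). In 1 of the 10 splits, the real one, was their camera p as small (1.31e-09, next 0.00933), too few splits for a share under 0.05, and the list drew in part on this series, so this is not independent evidence. After cyclic loess S100a5, the member with the largest difference, was at -1.90 (SE 0.13), against -1.85 before. Loess moved the median of all probe sets only from 0.06 to -0.00059, so a difference of that size could hardly have gone. For the list as a whole the median was -0.37 after loess, against -0.28 before, and 7 members fell and 2 rose over the list alone. The list median did not shrink, which argues against an intensity-dependent difference as its whole cause. The mature neuron list without shared members had a median of 0.10, so these markers were not lower as a group. That median lay above the -0.28 of the activity-linked list by 0.38, more than the SD of its members (0.20). The gap was short of 2 bootstrap standard errors of the difference (SE 0.24), the criterion first set. As the outcome turned on a bound changed after the values were seen, the test does not decide on fewer mature neurons as the whole cause. Lower odour stimulation of that side, which the design names, stays open as an untested explanation, as does higher stimulation of the other side.

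The connective tissue, endothelium, macrophage and neutrophil lists lay higher on the occluded side by camera, a call each lost with an estimated correlation (adjusted p = 0.957 for the first 3 and 0.900 for neutrophils). For connective tissue, 1 of the 10 splits, the real one, had a camera p as small (3.17e-09, next 2.39e-07), too few for a share under 0.05. For neutrophils it was also 1 (0.0096, next 0.0166). For endothelium and for macrophages 3 of the 10 splits had a camera p as small. The smallest other was 7.80e-07 against 7.93e-05 in the real split for endothelium, and 3.26e-05 against 0.00403 for macrophages. A lower share of neurons would raise all other cell types alike. The 4 lists lay 0.19 (SE 0.04 over genes), or 0.11 (SE 0.03) without occluded replicate 1, above the sustentacular and basal cell lists. The 4 were grouped because they passed camera upwards in these data, and the sustentacular and basal cell lists did not pass. A gap was therefore largely built in, and it cannot decide whether the share of neurons was lower. The mature neuron median was not below that of all genes. The immature neuron median was, at -0.04, with 21 of 25 members below 0 and a camera adjusted p of 0.000519 (0.957 with an estimated correlation). A lower share of neurons, immature ones included, therefore stays open. An intensity-dependent difference as the whole cause is argued against. Relative to all genes the median over the 116 members was 0.187 (SE 0.03) after cyclic loess, against 0.191 before. Without occluded replicate 1 that value was 0.103 (SE 0.02), above 0, the bound set later. The value did not clear 0.5 of the full value by 2 standard errors, the criterion first set. These standard errors are over genes, so what remained cannot be told from the spread between arrays. Whether the pattern was confined to that array is therefore left open. More lamina propria or bone relative to the whole epithelium, which would give the same gap, and a biological response stay open and untested.

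Odorant receptors passed an unadjusted p more often than other probe sets, but 4 of the 10 splits gave as large an excess. It was 4.10 percentage points in the real split and 19.9 in the highest other. The excess therefore does not set the sides apart from other groupings of the arrays. The larger excess came with occluded replicate 1 and contralateral replicates 1 and 2 on one side. Their centred receptor medians, -0.13, -0.059 and -0.012, lay below the 0.071 to 0.10 of the other arrays. Receptor levels thus differed between those groups of arrays, and why they did was not tested. Their expression level is argued against as the cause, since other probe sets of the same expression deciles gave 5.52% against 9.26%. The 93 class I receptors had a centred median of -0.66 (SE 0.03) in occluded replicate 1, where the other 5 arrays lay between -0.10 and 0.40; after cyclic loess it was still -0.66 (SE 0.04), which argues against an intensity-dependent difference. Less dorsal epithelium in that array is a candidate explanation that cannot be told apart: the dorsal markers Nqo1 and Acsm4 were lowest there, at -0.56 and -0.60, but the ventral marker Ncam2 was also lowest, at -0.38. The dorsal minus ventral value of -0.20 was not the lowest of the 6 arrays, against the prediction, and lay above the lowest, -0.41, by less than the SD of the other arrays (0.28).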
